A study of Homo sapiens with 4 samples.

How the data were processed

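Single-cell RNA libraries of the human ES cell line MEL1 were made on the ddSEQ platform with a 3′ whole-transcriptome kit. There were 4 libraries in 4 groups, 1 library each: ES cells, endoderm after 3 days of induction, and the same induction with crotonate or acetate. The deposited files hold UMI counts per gene and barcode. Per the submitters' processing notes, STAR, Subread, featureCounts 1.6.3 and UMI-tools 0.5.0 were used with the hg19 genome, and their order and settings are not given. The files listed 190560, 154706, 172856 and 174854 barcodes for ES, endoderm, crotonate and acetate, and 20055 genes in any library. Of these, 19972 Entrez numbers matched the RefSeq table at hand (GRCh38), where 18086 symbols were equal. A gene not listed in a library was taken as 0. The files listed 0 mitochondrially encoded genes, so a planned limit of 20% mitochondrial UMIs removed nothing and these genes were not analysed here.

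Cells were barcodes above the knee of the UMI curve, computed on barcodes with at least 100 UMIs, and with at least 500 genes. The lowest UMI counts among cells were 14058, 11728, 11155 and 17463. The knee falls inside the group of high-count barcodes, so a fixed minimum of 5000 UMIs was added as an alternative. Cells held 59.7%, 61.2%, 76.5% and 65.7% of all UMIs, with medians of 5735.5, 5258, 5455 and 6247.5 genes per cell. Scrublet, run at an expected doublet rate of 5%, called 12, 13, 5 and 1 cells, which were kept and left out in an alternative.

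The comparisons were endoderm against ES, crotonate against endoderm, acetate against endoderm, and crotonate against acetate. UMIs were summed over the cells of a library and scaled to its total (CPM). Genes with at least 20 CPM in the higher library were compared, and those at least 2-fold apart were counted. The interval of a ratio is the exact conditional (Clopper-Pearson) 95% interval of 2 Poisson counts, which covers counting error only. A count of 0 was set to 3 counts for a bound. No test was made, since no group has a replicate. Named genes follow a rule set before the data were examined. They are the 12 higher and 12 lower genes whose interval bound nearest to 1 is farthest from it, with at least 50 CPM in the higher library, leaving out mitochondrially encoded, ribosomal protein, Y-linked and related genes, pseudogenes and clone names, plus any member of a fixed list. NPPB was singled out for the closing section after its values were seen. Some genes that the rule names are not reported here.

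There were 23 gene lists, including the genes raised by HDAC inhibitors, and 7 sets of cell type markers. Later lists of YAP/TAZ-TEAD targets and amino acid response genes were written after some values had been seen. A list's members at least 1.5-fold higher or lower were counted. Its median log2 ratio has a 95% interval from 1000 Poisson draws and a percentile among 10000 random lists. Random members came from the 50 genes on each side in rank of expression.

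For shares of cells with a UMI and for clustering, each cell was thinned to 12400 UMIs, the 10th percentile of depth rounded to 100. Cells with fewer UMIs than the depth of thinning were left out, in the thinned alternatives as well. Barcodes with 100 to 500 UMIs were taken to stand for free RNA, which was not tested. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.6, and gave 5 clusters. Without the 1492 genes that were 1.5-fold apart between induced libraries or were markers, it gave 6. Clusters are given by number. The ratios to the shared endoderm library were correlated over 20 random splits of its cells and set against 100 simulations without an acid difference.

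Alternatives were fixed minimums of 1000 and 5000 UMIs, all barcodes, Scrublet calls left out, median-of-ratios scaling, a total without ribosomal protein genes, the mean of CPM per cell, limits of 5 and 100 CPM, and a pseudocount of 5 CPM. Others were subtraction of the free RNA profile at 10% of UMIs, unthinned cells, resolutions of 0.3 and 1, and clustering without markers. The 4 alternatives chosen after seeing the data were the 5000-UMI minimum, cluster 1 left out, cells without a SOX17 UMI left out, and clustering without the differing genes. Leaving out random cells used 20 draws. On simulated data, the 100 genes set 3-fold apart and the 100 set 4-fold apart were all recovered at 2-fold in each comparison. None of the other genes passed 2-fold, and 94.4% to 95.3% of their intervals held 1. These simulations hold counting error only. Metallothionein genes are similar in sequence and may share reads, and the strand of GATA6-AS1 reads was not checked. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (which includes Scrublet), anndata 0.12.19, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9. Random draws used seed 20.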

Results

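Gene expression was measured in single cells of MEL1, a human embryonic stem (ES) cell line. Droplet libraries of polyadenylated RNA were sequenced at the 3′ ends of transcripts. There were 4 libraries, 1 per group: undifferentiated ES cells, cells taken through a 3-day endoderm induction, and cells induced in the same way with crotonate or with acetate. Crotonate and acetate are short carboxylic acids, of which crotonate has the longer, unsaturated chain. The labels state the same 3 days of induction for both acids and no dose for either. Over all barcodes, the ES, endoderm, crotonate and acetate libraries held 8864891, 7792758, 14123088 and 10619489 UMIs (unique molecular identifiers, each marking 1 RNA molecule). The barcodes kept as cells numbered 232, 267, 549 and 268 in the same order. These cells held 5295089, 4772985, 10797380 and 6980133 UMIs, with medians of 19522, 15983, 16901 and 23236 UMIs per cell. With 1 library per group there was no test and no spread between replicates. Ratios therefore compare 2 libraries by UMI counts summed over cells and scaled to a common library size (CPM). Their 95% intervals, given in brackets, are exact conditional (Clopper-Pearson) intervals and cover counting error only.

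The first comparison, endoderm against ES, addressed what the 3-day induction itself looked like in these cells. Several transcripts of the primitive streak and of definitive endoderm were at or near 0 in the ES library and abundant after induction. Others were already present in ES cells, such as NODAL, a secreted signal, at 70.4 CPM, and KIT, a receptor kinase, at 20.4 CPM. SOX17 (Entrez 64321), a transcription factor required for endoderm formation, had 560 CPM after induction and no UMI in ES cells. With 0 set to 3 counts its ratio was 988, and its interval starts at 803. EOMES (Entrez 8320), a T-box factor of the mesendoderm, stood at 854 CPM against 0.189 CPM, and GATA6, a zinc finger factor of the endoderm, at 571 against 0.189 CPM. CXCR4, a chemokine receptor used as a surface marker of definitive endoderm, was 245-fold higher [118 to 610]. MIXL1, a homeobox factor of the streak, was 318-fold higher [189 to 581]. SOX2 (Entrez 6657), a core pluripotency factor, was 11.7-fold lower [9.45 to 14.7], at 19.1 against 223 CPM.

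Of 8183 genes with at least 20 CPM in either library, 875 were at least 2-fold higher and 536 at least 2-fold lower after induction. Among the named higher genes, CYP26A1, a retinoic acid degrading enzyme, reached 1482 CPM from 2.64 CPM. LHX1 stood at 602 against 0.567 CPM, FREM1 at 559 against 0.944 CPM, and the Nodal and BMP antagonist CER1 at 148 against 0.189 CPM. GSC had 138 against 0.189 CPM. The WNT inhibitor DKK1 and GATA6-AS1, a non-coding RNA antisense to GATA6, had no UMI in ES cells. With 0 set to 3 counts their ratios were 134 and 218, and their intervals start at 108 and 177. The named lower genes included 5 metallothioneins, small metal-binding proteins with closely similar sequences. MT1G was 71.3-fold lower [46.5 to 115], MT1H 36.7-fold, MT1E 26.0-fold, MT1X 13.3-fold and MT1F 10.1-fold. VSNL1, a neuronal calcium sensor, was 16.6-fold lower and LECT1 16.8-fold lower. The secreted WNT modulator SFRP2 was 8.60-fold lower, PTPRZ1 8.98-fold, AASS, a lysine-degrading enzyme, 8.08-fold, and CDKN1A, a cell cycle inhibitor, 9.32-fold.

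Gene lists fixed in advance were summarised by their members at least 1.5-fold higher or lower and by their median log2 ratio. All 15 measured definitive endoderm genes and all 11 measured primitive streak genes were higher, with medians of 6.80 [6.02 to 7.08] and 7.43 [5.86 to 7.56]. Measured genes had at least 20 CPM in either library. Members near 0 in ES cells could thus enter only by being high after induction, which in part sets these counts. Both list medians lay at percentile 100 of 10000 random lists matched on expression. Of 18 pluripotency genes, 12 were lower, with a median of -1.29 [-1.36 to -1.23] at percentile 0. DPPA4 stood at 331 against 1277 CPM and POU5F1 at 32.3 against 96.7 CPM, whereas TDGF1, a Nodal co-receptor, stood at 698 against 602 CPM. Of 10 Nodal pathway genes 7 were higher, among them the Nodal antagonists LEFTY1 at 1749 against 161 CPM and LEFTY2 at 972 against 28.7 CPM. Of 7 WNT targets, 6 were higher. The single measured later endoderm gene, APOA2, was also higher, at 23.3 against 0.189 CPM.

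Structural and metabolic genes differed between the ES and endoderm libraries as well. Of 6 mesenchymal genes 5 were higher, with N-cadherin (CDH2) at 692 against 36.1 CPM and vimentin (VIM) at 1288 against 137 CPM, and 1 was lower. Of 9 epithelial genes, 2 were higher and 2 were lower: the keratin KRT8 stood at 879 against 235 CPM and EPCAM at 305 against 694 CPM. Of 16 cholesterol synthesis genes 12 were higher, with a median of 1.15 [1.07 to 1.23], and none was lower. HMGCS1, which makes the precursor of mevalonate, stood at 1167 against 400 CPM. Of 20 oxidative phosphorylation genes 10 were lower and none was higher, with a median of -0.60 [-0.67 to -0.55]. Of 11 p53 targets 10 were lower, with a median of -1.37 [-1.48 to -1.17]. Of 11 unfolded protein response genes, 5 were higher and 2 lower, and of 20 histone acylation genes, 5 were higher and 1 lower.

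Further lists of metabolism, cell cycle, stress and other germ layers were also compared. Glycolysis genes had 3 higher and 4 lower of 16, with SLC2A3, a glucose transporter, at 1716 against 371 CPM and HK1, a hexokinase, at 117 against 282 CPM. Fatty acid oxidation genes had 2 higher and 1 lower of 13, and genes raised by HDAC inhibitors 2 higher and 2 lower of 6. S phase genes had 2 higher and 4 lower of 14, and G2 and M phase genes 3 lower and none higher of 15. Immediate early and heat shock genes had 2 higher and 2 lower of 11. Few genes of other germ layers passed 20 CPM. Of the mesoderm list BMP4 was higher (31.2 against 20.4 CPM) and KDR lower (16.6 against 27.8 CPM). NES of the neuroectoderm list was higher (324 against 210 CPM) and TFAP2C of the trophoblast and amnion list lower (5.45 against 28.3 CPM). A count of 0 in ES cells was set to 3 counts, and 2 members each of the endoderm, streak and WNT lists entered the medians in that way.

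**Figure D1:**
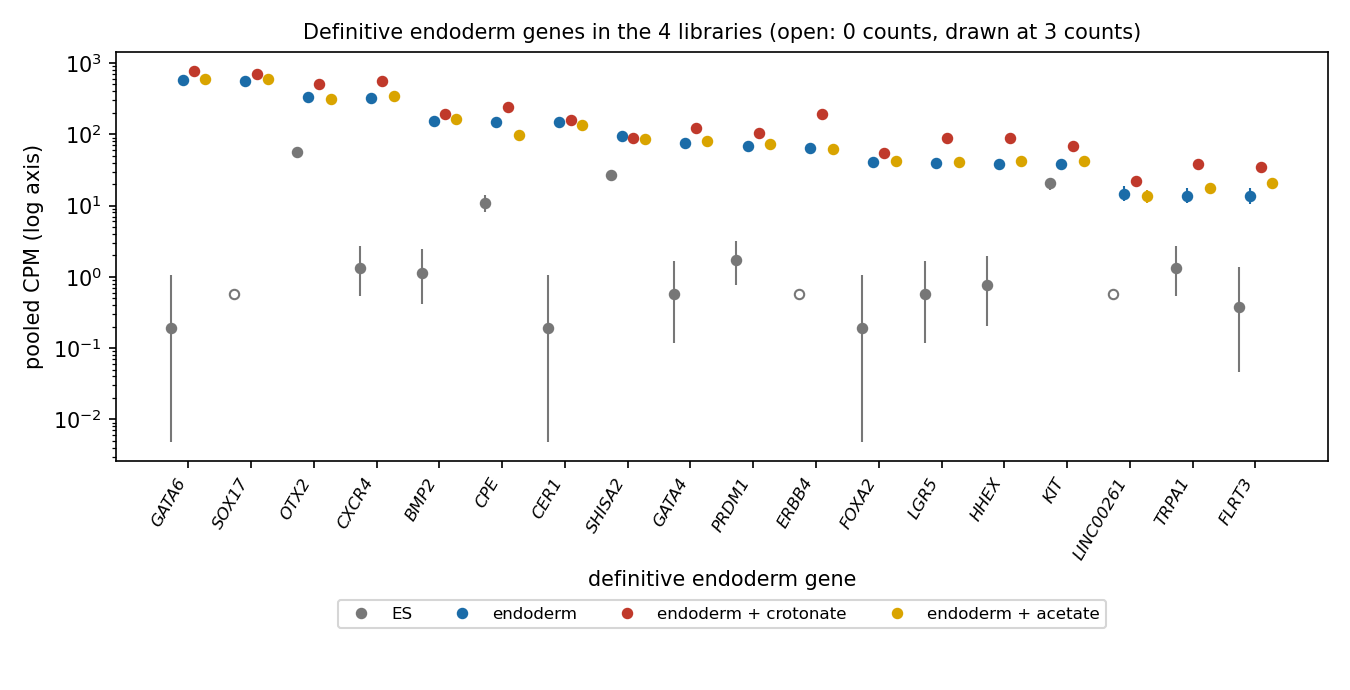
CPM summed over cells (log axis) of each definitive endoderm gene with at least 20 CPM in any library, for the ES, endoderm, crotonate and acetate libraries; lines are 95% Poisson intervals of the count, and open points are counts of 0 drawn at 3 counts. SOX17 stood at 0 in ES cells and at 560, 703 and 597 CPM in the 3 induced libraries, and the crotonate points lie highest for most genes, among them CXCR4 (551 CPM) and ERBB4 (190 CPM).

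The second comparison, crotonate against endoderm, addressed the question in the series title, whether crotonate goes with a difference in endoderm differentiation. Definitive endoderm genes were higher with crotonate: 11 of 18 measured genes were at least 1.5-fold higher and none was lower. HHEX, a homeobox factor of the anterior endoderm, was 2.32-fold higher [1.98 to 2.73], and ERBB4, a receptor tyrosine kinase of that list, 3.00-fold higher [2.66 to 3.39]. CXCR4 was 1.70-fold higher [1.61 to 1.80], at 551 against 323 CPM, and SOX17 1.26-fold higher [1.20 to 1.31], at 703 against 560 CPM. The matricellular proteins CTGF (Entrez 1490) and CYR61 were 5.24-fold [4.83 to 5.70] and 5.05-fold [4.58 to 5.58] lower.

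Across 7908 genes, 66 were at least 2-fold higher and 107 at least 2-fold lower in the crotonate than in the endoderm library. The named higher genes were led by FRZB (Entrez 2487), a secreted WNT antagonist, at 57.2 against 13.4 CPM, a ratio of 4.27 [3.30 to 5.61]. LGALS1, which encodes galectin-1, was 3.36-fold higher [3.09 to 3.67], at 427 against 127 CPM. NPPB, a natriuretic peptide precursor, was 2.45-fold higher [2.29 to 2.63]. C2orf88 was 2.87-fold higher, ERVH48-1, of endogenous retroviral origin, 2.45-fold, and TMEM27 2.32-fold. MGST2, a glutathione transferase, was 2.26-fold higher, PIK3R5, a regulatory subunit of a phosphoinositide kinase, 2.18-fold, and the reductase PTGR1 2.16-fold. Among the lower genes, the sulfotransferase CHST2 was 8.89-fold lower [7.39 to 10.8] and annexin ANXA1 5.70-fold [4.77 to 6.84]. IGFBP7 was 3.83-fold lower, DCLK1 3.81-fold, SPATS2L 3.75-fold, OLFML3 3.66-fold and the caveolar protein CAV1 3.31-fold. GAL, the precursor of the neuropeptide galanin, stood at 759 against 2244 CPM, 2.96-fold lower [2.87 to 3.04].

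By list, the definitive endoderm median was 0.67 [0.60 to 0.75], at percentile 100 of the random lists. TRPA1 was 2.74-fold higher, FLRT3 2.52-fold, the WNT target LGR5 2.21-fold and GATA4 1.63-fold. Both measured later endoderm genes were higher, HNF4A 2.85-fold [2.20 to 3.73] and APOA2 2.30-fold [1.87 to 2.84]. Epithelial genes had 4 higher and 1 lower of 10, with a median of 0.30 [0.23 to 0.41] at percentile 99.4. The keratins KRT19 and KRT18 were 1.89-fold and 1.74-fold higher, while E-cadherin (CDH1) had a ratio of 0.601 [0.521 to 0.695]. The median of 16 pluripotency genes was -0.08, at percentile 12.6. POU5F1 had a ratio of 0.388 [0.305 to 0.491] and the non-coding RNA ESRG of 0.281 [0.257 to 0.308], against 2.08 [1.98 to 2.20] for PODXL, a sialomucin. Among 12 primitive streak genes, EVX1 was 2.09-fold and GDF3 2.12-fold higher, and TBXT, a marker of the streak and early mesoderm, had a ratio of 0.288 [0.219 to 0.379]. The Nodal list had 1 higher member of 10, GDF3.

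The metabolic and stress lists fixed in advance had at most 2 members past 1.5-fold between the crotonate and endoderm libraries. None of 20 oxidative phosphorylation genes was 1.5-fold apart, and their median was 0.18 [0.15 to 0.23]. Of 13 fatty acid oxidation genes, EHHADH, a peroxisomal enzyme, was 2.01-fold higher [1.80 to 2.25] and CPT1A had a ratio of 0.665 [0.523 to 0.847]. Of 20 histone acylation genes, 1 was higher, the peroxisomal oxidase ACOX3, with a ratio of 1.63 [1.40 to 1.90], and none was lower. SLC2A1, a glucose transporter, was 3.12-fold lower [2.86 to 3.41] and the sole glycolysis gene of 15 past 1.5-fold. Of 4 genes raised by HDAC inhibitors, GADD45B was lower, with a ratio of 0.442 [0.366 to 0.533]. ASNS, asparagine synthetase, had a ratio of 0.449 [0.397 to 0.507] and was the sole unfolded protein response gene of 10 past 1.5-fold. IER2 was lower among 8 immediate early and heat shock genes, with a ratio of 0.523 [0.450 to 0.608]. No gene was 1.5-fold apart among 16 cholesterol synthesis, 14 S phase, 15 G2 and M phase and 4 p53 target genes. WNT targets had 1 higher (LGR5) and 1 lower (DKK4) of 7, and mesenchymal genes 1 higher (FN1) of 6. Single measured genes of other lineages were BMP4 (1.44 [1.19 to 1.74]), NES (0.575 [0.538 to 0.615]) and GATA3 (2.34 [1.72 to 3.24]).

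Per cell, SOX17 was found in more cells with crotonate. After each cell was thinned to 12400 UMIs, 448 of 476 crotonate cells held a SOX17 UMI, 94.1% [91.6 to 96.1]. The share was 69.3% [63.1 to 75.1] of 241 endoderm cells and 74.3% [68.6 to 79.4] of 268 acetate cells. In ES cells it was 0 of 232. With 0 set to 3 cells that is a share of 1.29%, a bound made otherwise than the intervals above. Thinning left out 0 ES, 26 endoderm, 73 crotonate and 0 acetate cells. Unthinned shares of SOX17 were 71.9%, 95.1% and 77.6%, at the median depths of 15983, 16901 and 23236 UMIs. CXCR4 was found in 64.3%, 91.0% and 70.1% of thinned endoderm, crotonate and acetate cells, against 1.72% of ES cells, and HHEX in 27.4%, 59.7% and 31.3%, against 1.29%. GATA6 was found in 81.7%, 96.8% and 84.0%, against 0.431%. The crotonate share was the lowest of the 3 for TBXT, with 18.7%, 5.46% and 22.0%, against 0 of 232 ES cells. It was also the lowest for POU5F1, with 31.1%, 13.7% and 32.1%, against 64.7% of ES cells. Unthinned shares in endoderm, crotonate and acetate cells were 68.5%, 92.5% and 75.7% for CXCR4, 35.2%, 68.9% and 47.4% for HHEX, and 82.8%, 98.0% and 87.7% for GATA6. They were 24.3%, 9.84% and 32.5% for TBXT and 40.8%, 20.4% and 52.2% for POU5F1. In ES cells the unthinned shares were 2.59%, 1.72%, 0.431%, 0% and 84.5% for these 5 genes, at a median depth of 19522 UMIs. Barcodes with 100 to 500 UMIs, not counted as cells, carried SOX17 at 462, 613 and 440 CPM in the endoderm, crotonate and acetate libraries. They carried CXCR4 at 318, 462 and 363 CPM, HHEX at 47.4, 134 and 52.8 CPM, and GATA6 at 476, 626 and 588 CPM. For each of these 4 genes the crotonate library was the highest there, as it was for the share of cells. That did not hold for all endoderm and streak genes. CER1 stood there at 302, 186 and 221 CPM, with crotonate the lowest, and EOMES at 800, 825 and 911 CPM, with acetate the highest. In cells CER1 stood at 148, 158 and 135 CPM. For HHEX the levels in barcodes with 100 to 500 UMIs were 122%, 149% and 124% of those in cells. TBXT stood there at 17.4, 9.31 and 23.6 CPM and POU5F1 at 26.9, 5.59 and 25.0 CPM, again in the order of crotonate lowest. In the ES library these barcodes held no SOX17 UMI, so ES cells do not bound the share of cells that free RNA alone could mark in the induced libraries.

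**Figure D2:**
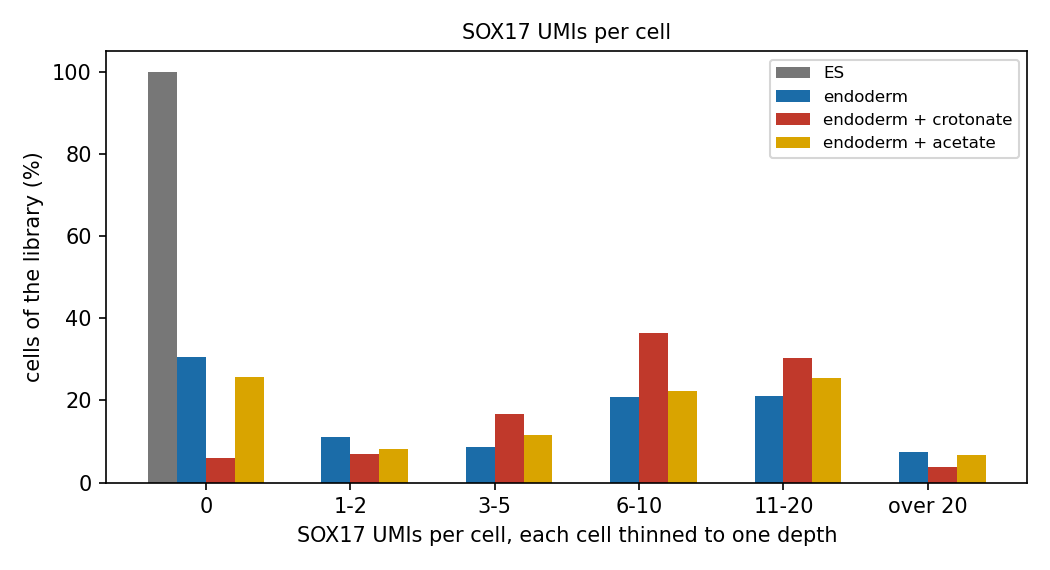
Share of cells (%) of the ES, endoderm, crotonate and acetate libraries by the number of SOX17 UMIs per cell, each cell thinned to 12400 UMIs; the bars of each library add up to 100%. All 232 ES cells stand at 0, and cells with at least 1 SOX17 UMI make up 69.3% of endoderm, 94.1% of crotonate and 74.3% of acetate cells.

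Clustering of the thinned cells set a group of induced cells with little SOX17 apart from the rest. With all variable genes, a cluster 1 held 44.8% of endoderm, 8.19% of crotonate and 36.9% of acetate cells. Its defining genes differed between libraries, so the clustering was repeated without the 1492 genes that were 1.5-fold apart between induced libraries or served as markers, a setting chosen after seeing the data. Cluster 1 then held 40.2% [34.0 to 46.7] of endoderm, 7.35% [5.17 to 10.1] of crotonate and 29.5% [24.1 to 35.3] of acetate cells. Cluster 1 of this second clustering, used from here on, held SOX17 at 128 CPM, against 596 to 1032 CPM in the other induced clusters, numbered 2 to 5. CXCR4 stood at 27.9 CPM, and TBXT at 67.7 CPM against at most 7.23 CPM in clusters 2 to 5. SOX2 stood at 56.9 CPM and the DNA methyltransferase DNMT3B at 766 CPM, below the 232 and 1214 CPM of cluster 0, while MIXL1 stood at 956 CPM. Among its first genes by fold over the other clusters were CHST2, CAV1 and ANXA1, all 3 of them among the named genes lower with crotonate. Cluster 0 held all 232 ES cells and 1 endoderm and 1 acetate cell. With 1 library per group, a cluster that is mostly 1 library may reflect that library.

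**Figure D3:**
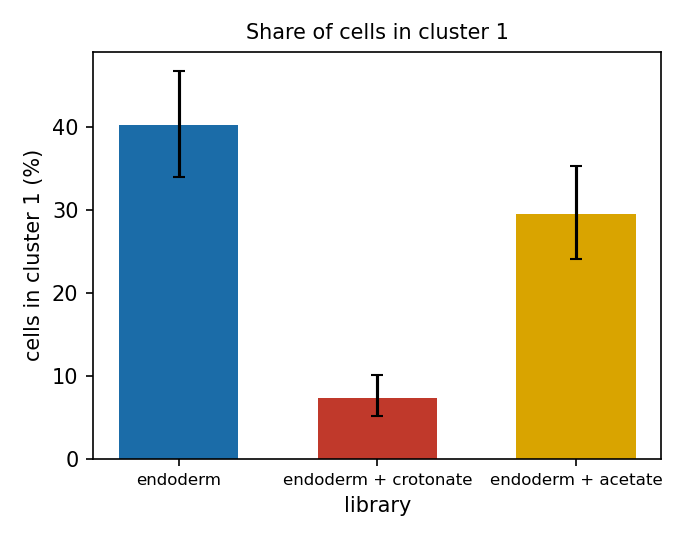
Share of cells (%) in cluster 1 of the clustering made without the genes that differed between induced libraries, for the endoderm, crotonate and acetate libraries; bars are shares and lines exact 95% binomial intervals. The share is 40.2% in endoderm, 7.35% in crotonate and 29.5% in acetate cells.

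Leaving cluster 1 out of both libraries, also chosen after seeing the data, left 27 genes at least 2-fold higher and 13 lower with crotonate, against 64 and 110 in all thinned cells, of which 21 and 9 were among the genes called in whole libraries. Definitive endoderm genes at least 1.5-fold higher then numbered 5 of 18, with a median of 0.23 [0.15 to 0.29]. Clusters 2 to 5 were pooled for further ratios, although their makeup differed between libraries. Of 143 endoderm and 441 crotonate cells in them, cluster 2 held 55 and 210, and cluster 3 held 60 and 138. Among thinned cells of clusters 2 to 5, LGALS1 was 3.10-fold higher with crotonate [2.72 to 3.55], FRZB 2.47-fold [1.81 to 3.45], ERBB4 2.11-fold [1.79 to 2.49] and HHEX 1.73-fold [1.40 to 2.16]. SOX17 had a ratio of 0.871 [0.821 to 0.923] and GATA6 of 0.965 [0.911 to 1.02] in those cells. The ratio of CTGF there was 0.736 [0.617 to 0.882], of CYR61 0.868 [0.691 to 1.10], and of CAV1 0.866 [0.646 to 1.17]. Other named lower genes stayed farther from 1 in those cells. CHST2 had a ratio of 0.233 [0.148 to 0.366], ANXA1 of 0.414 [0.262 to 0.660], SPATS2L of 0.519 [0.438 to 0.617] and GAL of 0.521 [0.492 to 0.552]. Inside cluster 1, with 35 crotonate and 97 endoderm cells, CTGF had a ratio of 0.138 [0.102 to 0.183] and CYR61 of 0.178 [0.128 to 0.242]. Leaving out induced cells without a SOX17 UMI instead gave 31 higher and 30 lower genes.

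**Figure D4:**
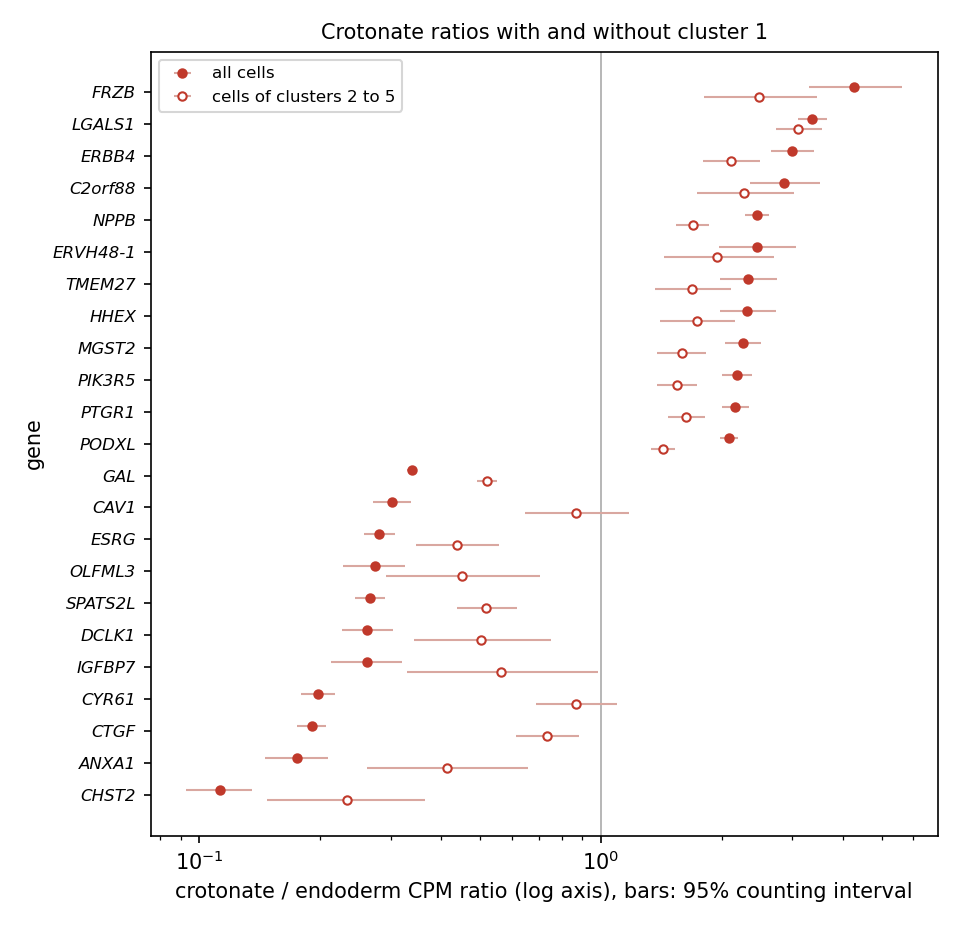
Ratio of CPM in the crotonate over the endoderm library (log axis) of named genes, in all cells (filled points) and in thinned cells of clusters 2 to 5 (open points); lines are 95% counting intervals. Open points lie nearer to 1 than filled points for each gene shown, by little for LGALS1 (3.10 and 3.36) and by much for CTGF (0.736 and 0.191).

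The third comparison, acetate against endoderm, addressed whether another short acid went with like differences. Only 12 of 7817 genes were at least 2-fold higher and 16 at least 2-fold lower. LGALS1 was 2.54-fold higher [2.32 to 2.78], DHRS2, a dehydrogenase, 2.46-fold [2.12 to 2.86] and the kinase LCK 2.28-fold [1.83 to 2.86]. Lower genes included IGFBP7, 2.46-fold [2.01 to 3.02], SPATS2L, 2.21-fold [2.04 to 2.41], and CTGF, 2.07-fold [1.93 to 2.22]. Definitive endoderm genes had 1 higher (FLRT3) and 1 lower (CPE) of 16, with a median of 0.07 [0.00 to 0.11]. SOX17 had a ratio of 1.07 [1.02 to 1.12] and CXCR4 of 1.07 [1.01 to 1.14] in acetate over endoderm cells.

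Other named genes higher with acetate had ratios from 1.59 for CKB, a creatine kinase, to 2.06 for IFI30, a lysosomal reductase. They included CRABP2, a retinoic acid binding protein (1.75 [1.58 to 1.93]), SP5, a WNT target (1.64 [1.46 to 1.84]), FABP5, a fatty acid binding protein (1.61 [1.45 to 1.78]), TECR, DHRS7B and CYBA. Of the lower genes, NPPB was 2.11-fold lower [1.91 to 2.33], CHST2 2.20-fold and the matrix protein TNC 1.98-fold. The secreted protease inhibitor SERPINE2 stood at 1332 against 2170 CPM. NLGN4X, ANXA3, NRP2, PRSS35 and PCDH10 were 1.73 to 1.99-fold lower. Cholesterol synthesis genes had no member past 1.5-fold among 16, with a median of -0.17 [-0.20 to -0.10] at percentile 0. Epithelial genes had none past 1.5-fold among 9, with a median of 0.31 [0.08 to 0.35] at percentile 99.98.

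Further lists of the acetate comparison had few members past 1.5-fold. The pluripotency list had 1 higher of 17 (SFRP2), the streak list 2 higher of 12 (SP5 and EVX1) and the WNT list 2 higher of 7 (SP5 and DKK4). Of 20 histone acylation genes, ACADSB was lower, with a ratio of 0.643 [0.499 to 0.827]. BAX was higher among 5 p53 targets, with a ratio of 1.52 [1.14 to 2.05], and CLU among 5 genes raised by HDAC inhibitors, with a ratio of 2.04 [1.51 to 2.79]. BMP4 of the 2 mesoderm genes was lower, with a ratio of 0.647 [0.510 to 0.820]. No member was past 1.5-fold among 10 Nodal, 6 mesenchymal, 15 glycolysis, 20 oxidative phosphorylation and 13 fatty acid oxidation genes. The same held for 14 S phase, 15 G2 and M phase, 8 immediate early and heat shock and 11 unfolded protein response genes, for the single later endoderm gene and for the single neuroectoderm gene. No trophoblast or amnion gene had 20 CPM. With cluster 1 left out, 15 genes were at least 2-fold higher and 16 lower with acetate, of which 7 and 4 were among the whole-library genes. CTGF had a ratio of 0.866 [0.706 to 1.06] in clusters 2 to 5 and of 0.439 [0.389 to 0.495] inside cluster 1.

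The fourth comparison set crotonate directly against acetate, 2 related acids, each with a 3-day induction and at doses the labels do not state. Of 7853 genes, 51 were at least 2-fold higher and 58 at least 2-fold lower with crotonate. NPPB was 5.18-fold higher [4.78 to 5.61], at 506 against 97.7 CPM, FRZB 4.30-fold [3.45 to 5.40] and the potassium channel KCNK12 3.91-fold [3.15 to 4.91]. CYR61 was 4.40-fold lower, at 54.5 against 239.7 CPM, and CHST2 4.05-fold lower [3.33 to 4.94]. Definitive endoderm genes were higher in 11 of 18 cases and lower in none, with a median of 0.67 [0.55 to 0.70]. Among them, CPE, a carboxypeptidase, was 2.48-fold, HHEX 2.11-fold and CXCR4 1.59-fold higher with crotonate.

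Further genes higher with crotonate than with acetate were MXRA5 (3.40-fold), EPSTI1 (3.32-fold), FAM20A (3.10-fold), ERBB4 (3.09-fold), FOXQ1 (2.58-fold), the chemokine receptor ACKR3 (2.51-fold) and ELOVL2, a fatty acid elongase (2.45-fold). Further lower genes were ESRG (3.71-fold), DCLK1 (3.46-fold), ANXA1 (3.31-fold), OLFML3 (3.07-fold), SEMA6A (2.78-fold), CTGF (2.53-fold), DKK4 (30.8 against 77.2 CPM), the cystine transporter SLC7A11 (2.46-fold) and LINC00458 (2.22-fold). Both later endoderm genes were higher, APOA2 2.76-fold and HNF4A 2.18-fold. Of 17 pluripotency genes, 4 were lower (POU5F1, SOX2, SFRP2 and ESRG) and PODXL was higher. Epithelial genes had 3 higher and 1 lower of 10, and streak genes 2 lower of 12 (TBXT and APLNR). The median of 10 Nodal genes was 0.26 [0.23 to 0.32].

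The 2 acid libraries were close for some other genes and lists and apart for others. EOMES had a crotonate over acetate ratio of 1.02 [0.987 to 1.05], LIN28A of 1.01 [0.977 to 1.04], TECR of 1.01 [0.896 to 1.14] and CKB of 0.985 [0.945 to 1.03], and IFI30 stood at 71.7 against 71.3 CPM. Oxidative phosphorylation genes had none of 20 past 1.5-fold and a median of -0.02 [-0.06 to 0.00]. None was past 1.5-fold among 16 cholesterol synthesis (median 0.19 [0.15 to 0.21]), 14 S phase (median -0.16 [-0.21 to -0.10]), 15 G2 and M phase and 5 p53 target genes. Glycolysis genes had 2 lower of 15, with SLC2A1 at a ratio of 0.438 [0.401 to 0.478] and HK1 at 0.649 [0.590 to 0.713]. Fatty acid oxidation had EHHADH of 13 higher, with a ratio of 1.83 [1.67 to 2.01], and histone acylation ACOX3 of 20, with 1.68 [1.47 to 1.92]. WNT targets had 1 higher and 1 lower of 6, mesenchymal genes 1 higher and 1 lower of 6, and mesoderm genes 1 higher (BMP4) and 1 lower (PDGFRA) of 2. The unfolded protein response list had 2 lower of 11 (ASNS and CHAC1), and the immediate early and heat shock list IER2 lower of 8. Among 5 genes raised by HDAC inhibitors GADD45B was lower, and single measured genes were NES (0.631 [0.593 to 0.671]) and GATA3 (3.22 [2.38 to 4.43]). With cluster 1 left out of both libraries, 24 genes were at least 2-fold higher and 8 lower, of which 22 and 8 were among the whole-library genes, and 6 of 18 definitive endoderm genes were at least 1.5-fold higher.

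The last comparison asked whether crotonate and acetate differed from the endoderm library in the same genes. Of 7718 genes tested in both, 9 were at least 2-fold higher in both, among 43 with crotonate and 10 with acetate, where independent lists would share 0.0557. They included LGALS1, DHRS2, IFI30, TECR and EVX1. There were 13 genes at least 2-fold lower in both, among 107 and 16, where independent lists would share 0.222, and these included CHST2, CTGF, IGFBP7 and SPATS2L. Both ratios share the endoderm library, which alone makes them agree. With endoderm cells split into 2 random parts, 1 per ratio, Pearson's r across 7611 genes was 0.29 (0.197 to 0.395 over 20 splits) and Spearman's rho was 0.24. Libraries simulated without an acid difference gave an r of 0.00 [-0.13 to 0.14]. The covariance was 0.0265, against 1.1e-05 in the simulation. With the whole endoderm library in both ratios, r was 0.476 against 0.586 [0.507 to 0.699] in the simulation, and the covariance 0.0381 against 0.0110. The parts are cells and not libraries, and genes are not independent replicates, so some of the excess may come from the shared endoderm library.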

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

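The tests that left cluster 1 out or looked inside it, the minimum of 5000 UMIs, and the ratio of shares without SOX17 at 1000 UMIs were chosen after the result was seen (for 5000 UMIs, after the barcode counts). The others in this part, among them the shares of cells with SOX17 at 1000 UMIs, were chosen before. NPPB, a natriuretic peptide precursor, lay on opposite sides of the endoderm library in the 2 acid libraries. It was 5.18-fold higher in the crotonate than in the acetate library, with 2.45-fold higher levels than endoderm for crotonate and 2.11-fold lower levels for acetate. Among cluster 1 cells the order was reversed, with a ratio to endoderm of 0.267 [0.112 to 0.551] for crotonate, from 8 UMIs, and 1.45 [1.07 to 1.97] for acetate. In clusters 2 to 5 the ratios were 1.69 [1.54 to 1.86] and 0.313 [0.265 to 0.368], so the whole-library order is that of clusters 2 to 5. NPPB was among the first genes of cluster 2, which held 55 of 143 endoderm, 210 of 441 crotonate and 81 of 188 acetate cells there. These ratios do not hold that makeup fixed. With 1 library per group, this difference was not tested.

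SOX17 was also present in barcodes with 100 to 500 UMIs, which were not counted as cells. It stood there at 462 CPM in the endoderm, 613 CPM in the crotonate and 440 CPM in the acetate library, or 82.5%, 87.1% and 73.8% of the level in cells. In the ES library no SOX17 UMI was found there, which allows up to 3.43 CPM by its 95% interval. Such barcodes may hold free RNA or damaged cells. With a minimum of 1000 UMIs the share of cells with SOX17 was 61.7% in the endoderm, 75.8% in the crotonate and 61.0% in the acetate library. Cells were thinned to 2500 UMIs there, which left out barcodes below that depth.

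The first pattern weighed is the difference between the crotonate and endoderm libraries. At 1 depth, the share of cells without SOX17 was 3.56 times higher in the endoderm library with a minimum of 5000 UMIs (2.37 from the nearest bounds). It was 1.58 times higher with a minimum of 1000 UMIs (1.24 from the nearest bounds). Cells are then thinned to 2500 instead of 7100 UMIs, and barcodes below these depths were left out. Depth or the choice of cells may thus account for part of that difference, and these values do not separate the 2. GC content and transcript length do not account for most of the gene differences, since 93.5% [88.7 to 96.7] of 170 genes with a 2-fold difference kept it after their trend was removed. Intervals of such percentages of genes, here and for the second pattern, are binomial over genes. Genes are not independent, so these intervals may be too narrow. Without cluster 1, 40 genes were 2-fold apart, against 163 to 239 after as many random cells were left out. A smaller share of cluster 1 cells is a candidate source, and so are differences inside cluster 1. There, CTGF had a ratio of 0.138 [0.102 to 0.183] and CHST2 of 0.265 [0.178 to 0.381], but IGFBP7 of 0.985 [0.694 to 1.38]. Leaving cluster 1 out removes both the share and these differences, so it cannot tell them apart. The makeup of clusters 2 to 5 differed too. Cluster 2, whose first genes include MGST2, NPPB and PTGR1, held 55 of 143 endoderm and 210 of 441 crotonate cells there. What this makeup adds to the differences was not tested. Culture, handling and an action of crotonate were not tested and stay open.

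The second pattern is the 37 genes at least 1.5-fold higher in both acid libraries, among them LGALS1 and DHRS2. With cluster 1 left out, 94.6% [81.8 to 99.3] had a counting interval above 1 in both. The genes were chosen at 1.5-fold from counts that include these cells, so a high percentage was likely in advance and does not decide. LGALS1 and DHRS2 were higher with both acids inside cluster 1 too, so the share of cluster 1 cells alone does not account for LGALS1 and DHRS2. How far that share adds to the differences of the 37 genes stays open. Of them, 62.2% [44.8 to 77.5] were still 1.5-fold higher in both with cluster 1 left out. After the GC and length trend was removed, 75.7% [58.8 to 88.2] stayed 1.5-fold higher in both, and the endoderm library lay below ES for 64.9% [47.5 to 79.8] (43.5% of all 7908 genes, which unlike these were not chosen for a low endoderm value), short of the share set beforehand for a library standing apart but with an interval that reaches it. Over the whole interval, which treats genes as independent, most of these genes kept the difference after the trend was removed. That argues against GC content or length as their main source. Still, the acetate log2 ratio had Spearman correlations of 0.17 with GC content and -0.30 with length across the genes compared. For crotonate they were -0.02 and -0.17. The interval crosses the share set beforehand for setting this explanation aside, so a part played by it stays open. An unusual endoderm library cannot be told apart from a shared effect of the acids for these genes. With 37 genes its interval crosses its bounds, and both ratios use 1 endoderm library.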

How the results depend on the processing

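Tests with a minimum of 5000 UMIs, with cluster 1 or cells without SOX17 left out, and with clustering without differing genes were chosen after the result was seen. Over all alternatives, 170 values of the main results stayed within their range and 63 moved, while 950 list medians stayed, 151 moved and 18 changed sign. Shares of cells with a UMI stayed in 67 cases and moved in 101. Median-of-ratios scaling moved none of the main results. Where no construction is named below, the cause was not tested.

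A limit of 100 CPM, which compares fewer genes, gave 267 genes higher and 178 lower for induction, 16 and 27 for crotonate, 2 and 4 for acetate, and 11 and 12 for crotonate against acetate. Definitive endoderm genes higher then numbered 7, 6, 0 and 5 in that order. Pluripotency genes lower numbered 1 for crotonate and 2 for crotonate against acetate, and the median of genes raised by HDAC inhibitors was 0.19 for the latter, against -0.19. A limit of 5 CPM, which adds genes with few counts, gave 1397 and 1069 for induction, 215 and 253 for crotonate, 70 and 81 for acetate, and 155 and 158 for crotonate against acetate. Pluripotency genes lower with crotonate numbered 4. With more genes in the list, the trophoblast and amnion median was 0.58 for induction, against -2.38, and -0.18 for crotonate, against 1.22.

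A pseudocount of 5 CPM, which shrinks ratios of genes with low CPM, gave 36 genes higher with crotonate, 6 higher with acetate, and 33 higher and 37 lower for crotonate against acetate. Summing all barcodes gave 41 genes higher with crotonate. The count of definitive endoderm genes higher with acetate, 1 (FLRT3), was 0 with all barcodes, the 5 CPM pseudocount, minimums of 1000 and 5000 UMIs, and either group of cells left out. The mesoderm median for crotonate, 0.52 from BMP4 alone, was -0.19 with all barcodes, -0.15 at 1000 UMIs, -0.12 at 5000 UMIs, -0.0756 without ribosomal protein genes in the total, and -0.40 without cells lacking SOX17.

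The share of cells with SOX17 was 61.7%, 75.8% and 61.0% in endoderm, crotonate and acetate with a minimum of 1000 UMIs, a setting that both admits more barcodes as cells and thins them to 2500 UMIs, and which of the 2 moved the shares was not tested. It was 91.6% in crotonate with a minimum of 5000. Thinning left out barcodes below 2500 UMIs in the first of these settings and below 7100 UMIs in the second. The share of cluster 1, 44.8%, 8.19% and 36.9% with all variable genes, was 36.0%, 4.87% and 25.1% without Scrublet calls, 33.7%, 5.10% and 27.2% in unthinned cells, and 32.1%, 5.14% and 24.5% with 5000 UMIs. In acetate it was 43.7% with 1000 UMIs, and 29.5% both without markers and without differing genes. Crotonate had the lowest share in each of these settings.

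Leaving cluster 1 out, which removes cells, gave 27 genes higher and 13 lower with crotonate, and 24 and 8 for crotonate against acetate. For acetate it gave 15 and 16, against 12 and 16, but 7 and 4 of these were among the whole-library genes. Definitive endoderm genes higher numbered 5 for crotonate and 6 for crotonate against acetate. Medians that changed sign for crotonate were primitive streak, -0.0459 against 0.10, Nodal, -0.0816 against 0.10, and S phase, 0.0263 against -0.05. Genes raised by HDAC inhibitors had 0.0212 for crotonate against acetate and -0.20 for induction, against 0.25, and neuroectoderm had 0.0873 for acetate, against -0.13, and -0.0632 for induction, against 0.63. Leaving out cells without SOX17 gave 31 and 30 genes for crotonate and 23 and 13 for crotonate against acetate, with 5 and 6 definitive endoderm genes higher. The Nodal median for crotonate was then -0.0435, and genes raised by HDAC inhibitors had 0.00528 for crotonate against acetate and -0.0474 for induction. With the whole endoderm library in both ratios, which shares its counting error, the correlation was 0.476, against 0.29 with split cells.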

Other observations

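DHRS2, a dehydrogenase, was higher with both acids inside cluster 1 as well as outside it. In cluster 1 it stood at 184 CPM with crotonate and 70.4 CPM with acetate, against 4.16 CPM in the endoderm library. These are ratios of 44.3 [18.2 to 140] and 16.9 [6.92 to 53.8], the endoderm value resting on 5 UMIs. In clusters 2 to 5 the ratios were 3.53 [2.68 to 4.73] and 4.67 [3.51 to 6.31]. EVX1, a homeobox factor of the streak, had ratios of 3.57 [2.02 to 6.86] and 4.21 [2.31 to 8.29] in clusters 2 to 5, and of 0.756 [0.251 to 1.92] and 1.28 [0.684 to 2.42] in cluster 1. Cluster 5, whose first genes include DHRS2 and the mitotic genes KIF20A, UBE2C, AURKA and PLK1, held 4.56% of endoderm, 9.66% of crotonate and 7.84% of acetate cells. These were 11, 46 and 21 cells, among 143, 441 and 188 cells of clusters 2 to 5. Shares over all cells therefore also depend on the size of cluster 1. The DHRS2 ratios in clusters 2 to 5 may in part reflect the share of cluster 5, which was not tested. No measured gene of the G2 and M phase list was 1.5-fold apart between the induced libraries.

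All tests of the next 2 hypotheses were chosen after the result was seen, and their lists were written after some values were known. CTGF and CYR61 are targets of YAP/TAZ-TEAD, which respond to cell tension and density, and lower activity of that pathway with crotonate was a first hypothesis. Of 13 measured targets 5 were lower and none higher with crotonate, with a median of -0.49 [-0.60 to -0.38]. Without CTGF and CYR61, which prompted the hypothesis, 3 of 11 were lower and the median was -0.48 [-0.53 to -0.25]. AXL, a receptor kinase, was 2.75-fold lower and NUAK2 2.17-fold lower, while ANKRD1 had a ratio of 0.910 [0.801 to 1.04]. With cluster 1 left out the median was -0.18 [-0.29 to -0.04] and none of 12 targets was past 1.5-fold, and without the 2 prompting genes it was -0.10 [-0.21 to 0.01]. Among cluster 1 cells, 7 of 13 targets were lower and none higher, with a median of -0.67 [-1.15 to -0.46], and without the 2 prompting genes 5 of 11 were lower, with a median of -0.58 [-0.95 to -0.36]. The smaller share of cluster 1 cells alone does not account for that difference, which rests on 35 crotonate cells. These cells also differed in cell type markers from the endoderm cells of cluster 1: SOX2 stood at 108 against 43.2 CPM, and the ratio was 2.21 [1.75 to 2.78] for SFRP2, a WNT modulator, 1.90 [1.40 to 2.56] for CER1, a Nodal inhibitor, and 1.44 [1.17 to 1.78] for GATA6. A different makeup of cells within cluster 1 may thus underlie the lower targets there, and was not tested. Outside cluster 1, lower activity may or may not be present, because the interval of the median spans the bound of -0.1. In the other comparisons the list had 6 higher and none lower of 13 for induction, 1 lower of 13 for acetate, and 4 lower of 13 for crotonate against acetate.

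Lower amino acid response with crotonate was a second hypothesis. Of 13 measured genes 7 were lower, with a median of -0.78 [-0.84 to -0.68], among them SLC7A11, a cystine transporter (2.84-fold), ASNS, asparagine synthetase (2.23-fold), and PSAT1, of serine synthesis (2.06-fold). SLC3A2, a subunit of amino acid transporters, had a ratio of 1.40 [1.32 to 1.48], and TRIB3, a target of the same pathway, of 0.991 [0.779 to 1.27]. With cluster 1 left out, 3 of 13 were lower and the median was -0.43 [-0.48 to -0.27], and among cluster 1 cells 7 of 13 were lower, with a median of -0.68 [-0.94 to -0.47]. Without ASNS, SLC7A11 and TRIB3, which other parts of the analysis had already named or listed, 5 of 10 were lower in the whole library, with a median of -0.60 [-0.69 to -0.54]. The median of these 10 was -0.41 [-0.46 to -0.25] with cluster 1 left out and -0.62 [-0.81 to -0.41] among cluster 1 cells. The share of cluster 1 cells alone does not account for either. The list may differ by an action of crotonate, medium, density or the makeup of cells within a cluster, which 1 library per group leaves open. It had 5 higher and 6 lower of 16 for induction, 1 lower of 14 for acetate and 7 lower of 14 for crotonate against acetate.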
